A study of Danio rerio with 5 samples.

How the data were processed

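Small RNA of 18 to 35 nt from zebrafish embryos at 48 hours post-fertilization was sequenced in 5 libraries, 2 of wild type, 2 of MZdicer and 1 of MZago2, per the labels. Reads were aligned with Bowtie 0.12.1, per the submitters' processing notes. The deposited files list alignments to zebrafish precursor miRNAs only, per the text that describes their columns: each line gives the strand, the precursor, the position, the sequence of a read and the number of other places where it aligned equally well. The files used here hold no count, ratio or normalised level. How adapters were removed, which release of the precursor set was used and how many reads were sequenced in all are not given in the sources used here. A level below is therefore a share of the reads that aligned to a precursor, and small RNAs from elsewhere in the genome were not analysed here.

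Each read was counted once, by its name, however many precursors it aligned to. miRNAs were recognised from 131 mature sequences written by hand before the data were examined. A read was given to a miRNA when it began within 2 nt of the mature 5′ end and matched the overlapping first 18 nt exactly. Sequences with the same 18 nt shared 1 name, which left 121. Of these, 6 matched no read and 3 fewer than 100 in all libraries together. Among the others, at least 99.1% of alignments fell on a precursor of the same number. The hand-written miR-144-5p matched 5 reads although the mir-144 hairpin had many, so reads of the hairpin as aligned are given for mir-144. The hand-written miR-430a matched 0 reads and miR-430b 116, although the hairpins of both were abundant, so these sequences are taken as faulty and hairpin reads are given for both; the miR-430b sequence still counts among the tested miRNAs and in the numbers of calls. Similar miRNAs, such as let-7 members or miR-92a and miR-92b, differ by few bases, and reads with errors in the first 18 nt were not assigned.

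Counts were divided by all reads in the file and multiplied by 1000000 to give CPM. The design fixed beforehand named count models as the main test if the files held a unit on which they are allowed. The files hold alignments, from which reads were counted here, and this was not taken as such a unit, so edgeR and DESeq2 were not used. The fallback written in the same design was: limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with 3 genotypes, 5 libraries, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The added 1 CPM shrinks fold changes of rare miRNAs in deep libraries. In MZdicer 2, where 3 reads are worth 24.6 CPM, a count of 0 can instead enlarge a fall. miRNAs were tested when their level reached 13.4 CPM in a library, the level of 10 reads in the median library, and their reads reached 15 in all, which kept 113. The lists were tested with fry and camera of limma. Single values were compared with exact permutation tests, shares and read counts were given exact 95% binomial or Poisson intervals, and 3 reads were taken as the floor of a library. A ratio of read counts has an exact interval conditional on the sum of both counts. Other tools were Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

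The test was tried on simulated reads for the 113 miRNAs and the design of MZdicer against wild type, in 20 sets with a dispersion of 0.2 and no batch difference. It called 1.14% of unchanged miRNAs, 9.50% of those changed 2-fold, 38.5% of those changed 4-fold and 97.5% of those changed 16-fold. The search for untemplated 3′ bases found 42264 of 42264 simulated tails and called 0 of 42264 inner mismatches tails.

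Read ends showed that 3′ adapters differed between replicates. The sequence CTGTAGGCACC occurred in 0.0892% of wild type 1 reads and 0.200% of MZdicer 1 reads and in 0% of the others, and TCGTATGCCGT in 0.00329% of wild type 2, 0.0123% of MZdicer 2 and 0.000313% of MZago2 reads. Across the 113 miRNAs, the difference between replicates 1 and 2 in wild type correlated with that in MZdicer at r = 0.909. The adapter was therefore added as a term in alternatives chosen after the data were seen. For MZdicer against wild type that term equals the replicate number. Adapter and allele are the same split within MZdicer.

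The named miRNAs were chosen by a rule fixed before the data were examined: miR-451, miR-144 and miR-486, the 10 most abundant in wild type, up to 10 rises and falls that passed the test, the 10 with the smallest fall in MZdicer, and the 2 most abundant members of each list. Fitted differences are given for the first groups, and levels for members of the lists and for the lone MZago2 library. Arms of 5p and 3p reads were compared for hairpins with 100 reads or more per library. Alternatives covered the pseudocount, the scaling, the filter, the match, each replicate left out, a replicate block and the adapter term. The planned share of long reads that start with U, and of paired reads on opposite strands, was left out, since alignments to precursors do not show the small RNAs it is about. Gene neighbours came from the RefSeq gene table of GRCz12tu, and no genome sequence was used.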

Results

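Small RNAs of 18 to 35 nt were sequenced from whole zebrafish embryos at 48 hours post-fertilization, with 40 embryos per sample. The series held 5 libraries of 3 genotypes: 2 of wild type, 2 of MZdicer and 1 of MZago2. MZ mutants lack both the maternal and the zygotic gene product, so no working protein is supplied by the egg. Dicer cuts the loop off hairpin precursors to release miRNAs. Argonaute2 (Ago2) binds miRNAs and is the Argonaute protein that can cleave RNA. The 2 MZdicer libraries came from embryos of different dicer alleles, hu715 (replicate 1) and hu896 (replicate 2), and MZago2 came from embryos of a single ago2 allele. Messenger RNA of dicer or ago2 was not measured, so the genotypes rest on the labels. The study compared the genotypes to ask whether any miRNA is made without Dicer and whether such a route needs the cleaving activity of Ago2.

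The deposited alignments held 748872 and 1700858 reads in wild type, 332577 and 121964 in MZdicer and 12159778 in MZago2. Levels are given in CPM, the reads of a miRNA times 1000000 over all reads aligned to miRNA precursors, so each is a share of these reads and not an amount per embryo. Intervals are exact 95% intervals and cover counting error only. The labels do not say that replicates came from separate crosses, so p-values measure only the spread between these samples. Replicate 1 of wild type and of MZdicer carried remnants of a 3′ adapter starting with CTGTAGGCACC, and the other 3 libraries carried remnants of one starting with TCGTATGCCGT. Across the 113 tested miRNAs, log2 levels of the wild type libraries correlated at r = 0.712 with each other, while r was 0.823 for wild type 1 with MZdicer 1 and 0.858 for wild type 2 with MZdicer 2. miRNAs are not independent replicates. Levels per library or differences within each adapter are therefore given beside most pooled values. Instrument names within the read names were the same for wild type 2 and MZdicer 2. They differed for wild type 1, MZdicer 1 and MZago2. Genotype and instrument therefore cannot be told apart within the first adapter, or between MZago2 and wild type 2.

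miR-451, an erythroid miRNA whose stem is too short for Dicer, had the largest fitted difference of the 113 tested miRNAs between MZdicer and wild type. With the second adapter alone, miR-122, let-7b, miR-223 and miR-187 had larger downward values. They had 0 reads in MZdicer 2, where 3 reads are worth 24.6 CPM. The added 1 CPM sets the size of those values, so larger falls are not shown. miR-451 had 397 CPM (95% interval 353 to 444) and 243 CPM (221 to 268) in the wild type libraries. In MZdicer it had 33893 CPM (33281 to 34513) and 8953 CPM (8432 to 9498). In MZago2, a single read of miR-451 was found, 0.0822 CPM (0.00208 to 0.458), although 3 reads of that library would be worth 0.247 CPM. Within adapters, MZdicer exceeded wild type by a ratio of 85.5 (76.2 to 96.2) for replicate 1 and 36.8 (32.8 to 41.3) for replicate 2. MZago2 over wild type 2, which shares its adapter, gave a ratio of 0.000338 (8.53e-06 to 0.00189).

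**Figure D1:**
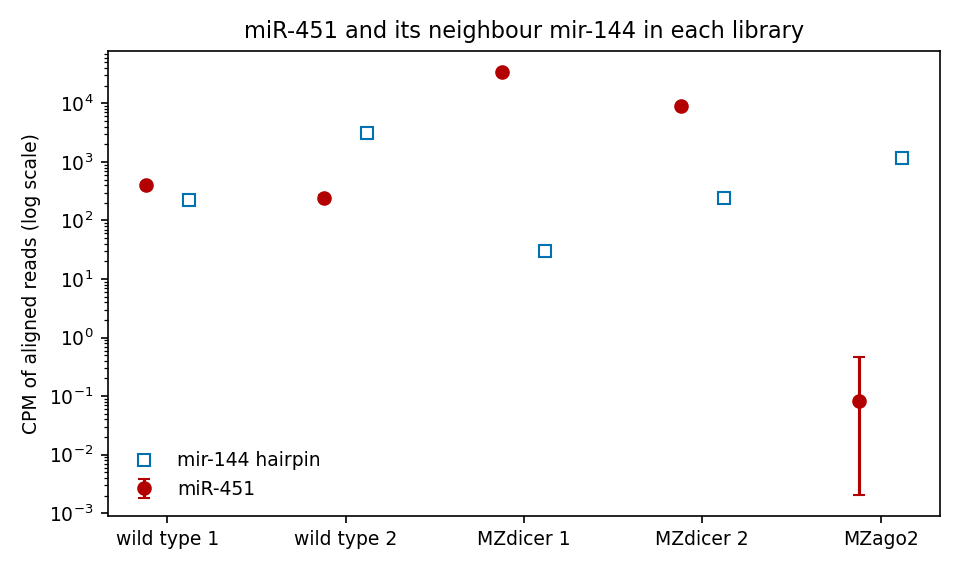
CPM, on a log axis, of miR-451 (filled circles, with exact 95% counting intervals) and of the mir-144 hairpin (open squares) in each of the 5 libraries. miR-451 lay at 33893 and 8953 CPM in MZdicer and at 0.0822 CPM in MZago2, while the mir-144 hairpin had 1181 CPM in MZago2.

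In the fit to all 5 libraries, on the log2(CPM + 1) scale, miR-451 differed by 5.80 ± 1.32 (SE) between MZdicer and wild type (limma, adjusted p = 0.427) and by -8.17 ± 1.62 between MZago2 and wild type (adjusted p = 0.207). Neither passed the threshold of 0.05. The difference between MZago2 and MZdicer did: miR-451 fell by 13.97 ± 1.62 (limma, adjusted p = 0.00952), and MZago2 lay below both MZdicer libraries. The lone MZago2 library is assumed to vary like the other groups. With the adapter as a term, a fit chosen after the data were seen, the differences were 5.80 ± 0.69, -7.51 ± 0.91 and -13.32 ± 0.91, with adjusted p of 1.55e-11, 3.98e-11 and 1.04e-25. Over the alternatives counted per listed miRNA, the adjusted p of miR-451 ran from these values up to 0.983, 0.988 and 0.0164. Counted per precursor family, another choice made after the data were seen, mir-451 had limma adjusted p of 0.237, 0.466 and 0.0256, and of 0.0200, 0.0735 and 0.00708 with the adapter term. The fit with the adapter term has 1 residual degree of freedom, and for listed miRNAs it gives each the same pooled error.

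miR-451 reads were also longer in MZdicer. Longer reads were not particular to miR-451. Reads of 25 to 30 nt had a larger share in MZdicer for 39 of 40 other 5p miRNAs with the first adapter. With the second this held for 25 of 33. Their median shares in MZdicer were 2.46% and 1.06%. Reads matching the hairpin without mismatch from the miR-451 5′ end peaked at 23 nt in wild type, with 74.4% and 38.8% of such reads in AAACCGTTACCATTACTGAGTTT. In MZdicer, 37.1% and 20.4% had this length, and a second peak lay at 26 nt (AAACCGTTACCATTACTGAGTTTAGT), with 33.8% and 29.5% against 1.45% and 1.0% in wild type. Reads of 24 nt or more made up 7.25% (4.11 to 11.7) and 6.25% (4.09 to 9.09) in wild type, and 59.5% (58.5 to 60.4) and 70.5% (67.5 to 73.4) in MZdicer. With 3′ ends left free to mismatch, these shares were 22.3% and 7.02% in wild type and 60.8% and 73.9% in MZdicer. Without mismatch, the longest read reached 30 nt, AAACCGTTACCATTACTGAGTTTAGTAATG. Reads from the 3p side of the hairpin numbered 3 and 4 in wild type, 19 and 4 in MZdicer and 5 in MZago2. In MZago2 they made up 5 of the 6 reads of the whole mir-451 hairpin.

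**Figure D2:**
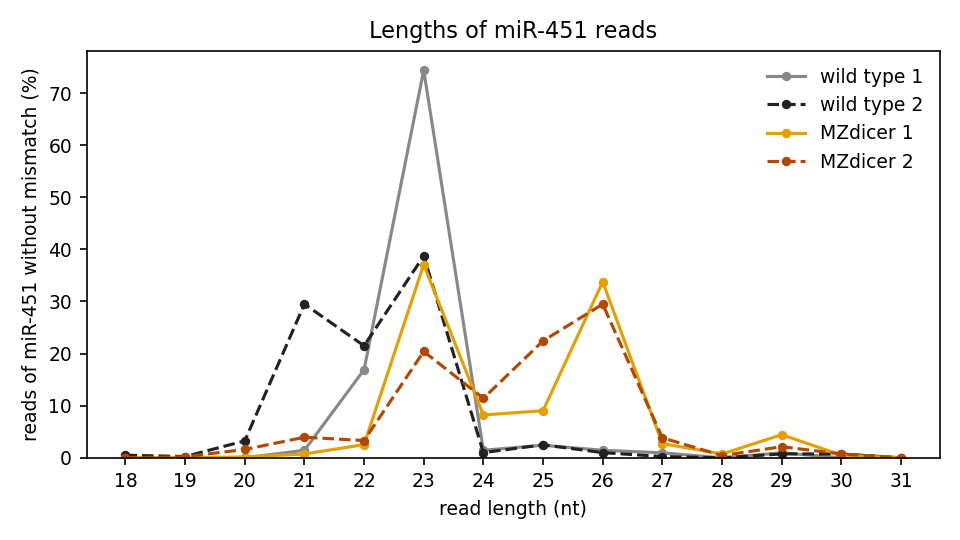
Length of miR-451 reads without mismatch, as a percentage of such reads in each library, against read length in nt; solid lines are replicate 1 and dashed lines replicate 2. Wild type peaked at 23 nt, and MZdicer had a further peak at 26 nt, with 33.8% and 29.5% of reads.

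mir-144, which is processed by Dicer, is the neighbouring gene of mir-451 with no annotated gene between them in the GRCz12tu assembly. Reads of the mir-144 hairpin came to 220 and 3138 CPM in wild type, 30.1 and 238 CPM in MZdicer and 1181 CPM in MZago2. Within adapters, MZdicer over wild type gave ratios of 0.136 (0.0642 to 0.257) and 0.0758 (0.0507 to 0.109). MZago2 over wild type 2 gave 0.376 (0.365 to 0.388), and over wild type 1, which has the other adapter, 5.36 (4.60 to 6.29). Mature miR-144-3p was sparse, at 158 and 4.12 CPM in wild type, 27.1 and 8.20 in MZdicer and 0.658 in MZago2. Its fitted difference was -0.83 ± 1.87 for MZdicer and -4.10 ± 2.29 for MZago2 against wild type, with limma adjusted p of 0.885 and 0.989; within the first and second adapter MZdicer differed by -2.50 and 0.85. No read matched miR-486, another erythroid miRNA; no precursor of that name was among those with reads.

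The comparison of MZdicer with wild type asked which miRNAs lose reads without Dicer. let-7d, a member of the let-7 family that marks differentiated cells, had 2703 and 1096 CPM in wild type and 111 and 49.2 CPM in MZdicer. miR-429, of the epithelial miR-200 family, had 10066 and 1870 CPM against 226 and 82.0. miR-430c, a member of the family that clears maternal messenger RNA, had 10927 and 9225 CPM against 2123 and 1082. miR-184 differed by -3.21 and -3.09 within the adapters. The muscle miRNA miR-206 had 117362 and 207830 CPM in wild type and 60582 and 95700 in MZdicer, and the neural miRNA miR-9-5p had 140609 and 115736 against 34239 and 43013.

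Of the 113 tested miRNAs, 55 were lower and 33 higher in MZdicer within both adapters, 24 went in opposite directions, and miR-193a had 0 CPM in both libraries with the second adapter. By more than 2-fold in both, 35 were lower and 15 higher. The fit without an adapter term called 0 miRNAs (limma, 6 at unadjusted p < 0.05: miR-451, let-7d, miR-429, miR-223, miR-122 and let-7b, named after their values were seen). With the adapter as a term, 15 rose and 32 fell. Of those at unadjusted p < 0.05, miR-223, miR-122 and let-7b had 0 reads in MZdicer 2, so the size of their fall there is uncertain. The same holds for miR-187, miR-338, miR-430b and miR-489, which were among the 32. The median difference of all tested miRNAs was -0.38, and it became -0.29 with trimmed-mean scaling, -0.28 with median-of-ratios scaling and -1.03 with reads that matched no listed miRNA as the library size. In MZdicer those unmatched reads numbered 148499 and 51223. The hairpins of mir-2190/mir-2198 had 68687 and 20660 reads there, against 98 and 57 in wild type, which enlarges this library size in MZdicer. They are also part of the main total, with 206530 and 169394 CPM in MZdicer, and so lower the CPM of every other miRNA there. The median of -0.38 and the numbers of lower and higher miRNAs were not computed without this family. Reads were simulated for the design of this comparison and 113 miRNAs, with a dispersion of 0.2 and no batch differences. In them the test called 38.5% of 4-fold and 97.5% of 16-fold changes. These rates do not carry over to the real libraries, where the wild types differed from each other by more than 2-fold for 76 miRNAs. Differences of 5.80 for miR-451 and -5.16 for miR-122 on the log2(CPM + 1) scale were not called. For miR-122 the values within the adapters were -3.96 and -6.35, the second from 0 reads in MZdicer 2, so its size is uncertain. The 0 calls therefore do not show that large changes were absent.

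**Figure D3:**
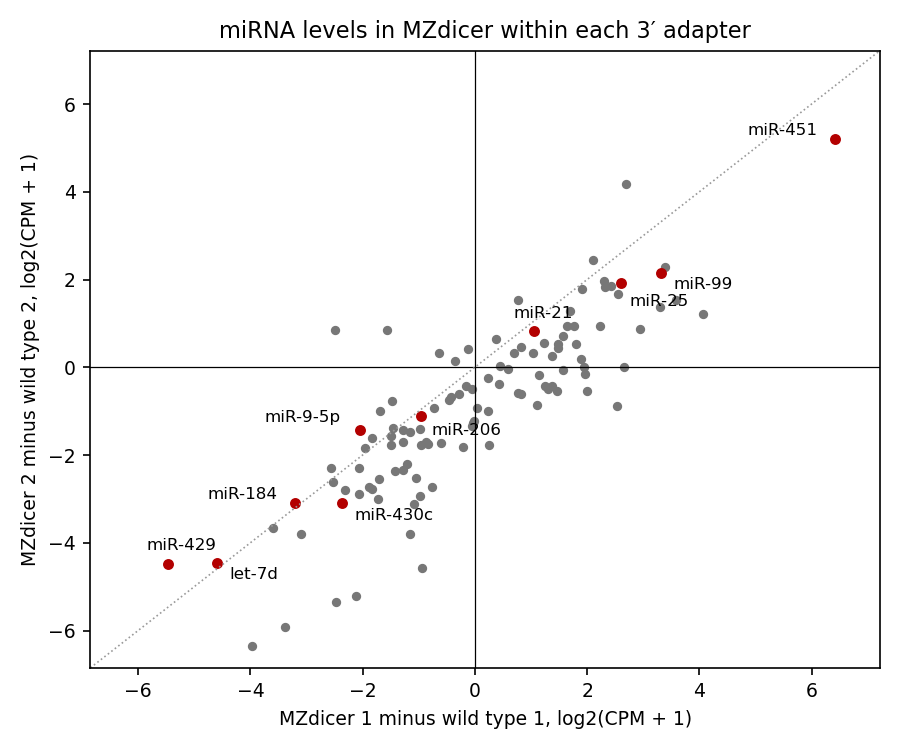
Difference in log2(CPM + 1) between MZdicer and wild type for the 113 tested miRNAs (points), in the libraries with the first 3′ adapter (horizontal axis, replicate 1) and with the second (vertical axis, replicate 2); the dotted line marks equal differences. miR-451 lay at 6.41 and 5.20, and let-7d at -4.59 and -4.45.

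Among the most abundant listed miRNAs, fitted differences in MZdicer were -1.04 ± 1.23 for miR-206, -1.73 ± 1.20 for miR-9-5p, 0.94 ± 1.80 for miR-21, -1.48 ± 1.76 for miR-20a, -3.15 ± 1.93 for miR-184 and -0.60 ± 1.70 for miR-1, which is expressed in muscle. For miR-181a the difference was -0.82 ± 1.52. The Hox-linked miRNAs gave -0.01 ± 1.20 for miR-10b/miR-10d, 0.40 ± 1.29 for miR-10a and -0.61 ± 1.25 for miR-10c. Within the first and second adapter, differences were -0.95 and -1.12 for miR-206, -2.04 and -1.43 for miR-9-5p, 1.06 and 0.83 for miR-21, -1.28 and -1.69 for miR-20a, -0.46 and -0.74 for miR-1, -0.72 and -0.92 for miR-181a and -0.01 and -1.22 for miR-10c. They went in opposite directions for miR-10a (1.30 and -0.50) and miR-10b/miR-10d (0.23 and -0.24). The smallest limma adjusted p among these was 0.649, for miR-184. miR-9-5p and miR-184 fell in the fit with the adapter term, with adjusted p of 0.0344 and 0.000129. The 10 miRNAs with the smallest fall or a rise, among those with 100 CPM or more in wild type, were miR-451, miR-146a, miR-135, miR-99, miR-101a, miR-199-3p, miR-219, miR-25, miR-124 and miR-92b. Each was higher in MZdicer within both adapters, and each rose in the fit with the adapter term. miR-99 had 1131 and 552 CPM in wild type and 11206 and 2460 in MZdicer, a difference of 2.73 ± 1.37. miR-25 had 1413 and 1836 against 8606 and 6986, a difference of 2.27 ± 1.20. miR-199-3p, a mesenchymal miRNA, differed by 2.33 ± 1.25, miR-219 by 2.28 ± 1.20 and miR-92b by 2.13 ± 1.22. miR-135 (61.4 and 1067 CPM in wild type), miR-146a (8.01 and 2659), miR-101a (9.35 and 1038) and the neural miR-124 (4783 and 157) differed more between the wild type libraries than their fitted differences of 2.83 ± 1.84, 3.43 ± 3.72, 2.56 ± 2.54 and 2.14 ± 2.36.

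Of 15 lists of tissue and cluster miRNAs fixed before the data were examined, 0 passed the directional test in MZdicer (fry of limma, 1 at unadjusted p < 0.05; camera called 0). Calls per list below are those of the fit with the adapter term, beside 0 in the fit without it. For the let-7 family 4 of 7 members fell and 0 rose (fry, adjusted p = 0.125), with let-7a/let-7c at 6276 and 9154 CPM in wild type against 1269 and 1320 in MZdicer. In the miR-430 list miR-430c fell. The hand-written miR-430a and miR-430b did not match the abundant reads of their hairpins, which as aligned had 105293 and 36592 CPM in wild type against 14367 and 5657 in MZdicer for mir-430b, and 38362 and 11708 against 7003 and 1459 for mir-430a/mir-430i; both fell with the adapter as a term (limma, adjusted p = 0.0354 for each), while mir-430c counted in this way did not pass (adjusted p = 0.110). Of the epidermal and epithelial list 3 of 5 members fell, among them miR-429, while miR-205 had 9779 and 1597 CPM in wild type and 9992 and 836 in MZdicer. Of the muscle list 2 of 5 fell (miR-133c and miR-499), and all 5 were lower within both adapters. In the sensory list 1 of 3 fell, miR-183, and miR-182 had 668 and 15194 CPM against 439 and 4583. The gut and liver list had 2 of 5 members that fell, the pancreatic miR-217 and the hepatic miR-122, while miR-192 had 46.7 and 2980 CPM against 102 and 1632.

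Of the neural list 2 of 10 rose (miR-219 and miR-124) and 2 fell (miR-9-5p and miR-137). By exact match miR-9-3p, from the other arm of the miR-9 hairpin, had 9373 and 1623 CPM in wild type against 29070 and 3140. These were 7019 and 2761 reads in wild type and 9668 and 383 in MZdicer. With 1 mismatch allowed it had 13132 and 26301 reads in wild type and 12028 and 1289 in MZdicer. The exact match thus missed most miR-9-3p reads in wild type 2 and MZdicer 2. Per aligned read, the count with 1 mismatch was lower in MZdicer 2 than in wild type 2, the opposite direction. Of the list of miR-17-92 clusters 4 of 10 rose (miR-25, miR-92a, miR-92b and miR-19b) and 2 fell (miR-18a and miR-363), while miR-93 had 11618 and 2569 CPM against 11258 and 1812. These 4 rises include reads with untemplated 3′ T. In MZdicer it ended 42.6% and 29.7% of reads for miR-25, 3.82% and 7.17% for miR-92a, 17.7% and 21.6% for miR-92b and 27.5% and 14.2% for miR-19b. In wild type the shares were 2.79% and 1.23%, 1.29% and 1.93%, 4.80% and 5.11%, and 2.97% and 1.16%. In the myeloid and haematopoietic list miR-146a and miR-155 rose and miR-223 fell, and miR-142a-3p had 18.7 and 67.0 CPM against 9.02 and 24.6. From the cartilage and mesenchyme list miR-199-3p rose, miR-140-5p and miR-143 fell, and miR-140-3p had 419 and 9938 CPM against 926 and 8740. miR-99 rose in the miR-99, miR-100 and miR-125 list, with miR-100 at 1910 and 2459 CPM against 4537 and 1828 and miR-125b at 1975 and 1800 against 7355 and 2066, and miR-196a rose in the Hox-linked list. No member was called in the endothelial list, where miR-126a-3p had 1058 and 1328 CPM against 589 and 394 and miR-126a-5p 114 and 300.4 against 397 and 435, or in the endocrine list, where miR-375 had 1715 and 219 CPM against 604 and 73.8 and miR-7a 296 and 151 against 385 and 238. In the erythroid list, adjusted over the list alone, 1 of 2 members was called in each contrast, miR-451. Adjusted over the list alone, the fit without an adapter term called 0 members of any other list in the 3 contrasts.

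Whether Ago2 is needed for miRNAs other than miR-451 was asked by comparing MZago2 with wild type. Of the 10 most abundant listed miRNAs of wild type, in MZago2 miR-206 had 188955 CPM, miR-9-5p 90170, miR-21 103457, miR-1 58084, miR-184 42058, miR-181a 18376 and miR-10a 18036. miR-20a had 14886 CPM, miR-10c 14342 and miR-10b/miR-10d 9448. Some hairpins outside the listed miRNAs were as abundant: in MZago2 those of mir-430b had 41448 CPM, of mir-203b 33590 and of mir-430a/mir-430i 12943. Of the miRNAs low in MZdicer, let-7d had 1658 CPM in MZago2, miR-429 1656, miR-430c 11105, let-7a/let-7c 14250 and miR-217 16446. Against wild type 2, 26 of 113 miRNAs differed by more than 2-fold, and against wild type 1, which has the other adapter, 74. The wild type libraries differed from each other by more than 2-fold for 76. The fit called 0 miRNAs (limma, 1 at unadjusted p < 0.05, miR-451). With the adapter as a term miR-451 fell and miR-219, a neural miRNA, rose by 3.35 ± 0.91 (adjusted p = 0.0206), with 234 and 172 CPM in wild type and 1877 in MZago2.

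Other list members in MZago2 were miR-182 with 25604 CPM, miR-183 with 12458, miR-140-3p with 12384, miR-93 with 5727 and miR-9-3p with 4011. The exact match took 48776 miR-9-3p reads there, against 375457 with 1 mismatch allowed, so its level is too low. miR-143 had 3828 CPM, miR-192 3515 and miR-146a 3889. Lower levels were those of miR-100 (1726 CPM), miR-125b (1547), miR-126a-3p (1388), miR-205 (789), miR-7a (367), miR-126a-5p (170.4), miR-375 (157) and miR-142a-3p (138). No list passed the directional test against wild type (fry of limma, 0 at unadjusted p < 0.05). The camera test with a preset correlation called 1 list, the erythroid one of miR-451 and miR-144-3p (adjusted p = 6.03e-06), and adjusted p = 0.759 with an estimated correlation.

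The direct comparison of the mutants called 1 of 113 miRNAs, miR-451 (limma, 4 at unadjusted p < 0.05: miR-451 lower and let-7d, miR-217 and miR-223 higher in MZago2, the last 3 named after their values were seen). miR-223 had 0 reads in MZdicer 2, so the size of its difference is uncertain. With the adapter as a term 29 rose and 8 fell. Those that rose in MZago2 relative to MZdicer included let-7d by 5.08 ± 0.91, miR-429 by 4.56 ± 0.91, let-7a/let-7c by 3.31 ± 0.91 and miR-430c by 3.18 ± 0.91. Besides miR-451, miR-146a, miR-99, miR-25, miR-92b, miR-27c, miR-92a and miR-128 fell. No list passed the directional test (fry, 2 at unadjusted p < 0.05). The let-7 list passed fry's mixed test (adjusted p = 0.0312, directional adjusted p = 0.151), with 6 of 7 members higher in MZago2. camera called the erythroid list with a preset correlation (adjusted p = 0.00143), and adjusted p = 0.785 with an estimated correlation.

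The use of hairpin arms was compared between MZago2 and wild type. Of 124 hairpins with 100 or more reads in each of these 3 libraries, 115 had the same main arm in all 3. Shares of 3p reads lay outside the range of the wild type libraries by 10 percentage points or more for 5 hairpins. The mir-128 hairpin had 83.3% and 85.9% of reads from the 3p arm in wild type and 48.9% (47.3 to 50.4) in MZago2, and mir-219 had 65.3% and 54.2% against 19.1% (18.6 to 19.5). Higher 3p shares were found for mir-15a, with 0% and 5.67% against 25.3% (23.4 to 27.3), mir-125a, with 3.20% and 24.6% against 39.4% (38.3 to 40.5), and mir-125c, with 13.2% and 15.1% against 27.7% (27.1 to 28.3). The wild type libraries themselves were 10 points or more apart for 26 of the 124 hairpins, and no test was made of these shares. In MZdicer, 3p shares were 96.9% and 87.8% for mir-128, 55.5% and 22.1% for mir-219, 11.6% and 31.5% for mir-125a, and 4.73% and 10.8% for mir-125c. For mir-15a the MZdicer reads were too few. With a minimum of 1000 reads, 1 of 63 hairpins lay outside by that much, mir-125a, whose wild type libraries were 21.4 points apart. mir-128 (902 and 950 wild type reads), mir-219 (642 and 725), mir-15a (384 and 247) and mir-125c (493 in wild type 1) did not reach this minimum. Their shifts were therefore not examined at that depth.

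Read lengths and the share of listed miRNAs were also compared between genotypes. Reads that matched one of the listed miRNAs made up 62.9% and 79.5% of aligned reads in wild type, 55.3% and 58.0% in MZdicer and 81.0% in MZago2. Their mean was 71.2% ± 11.7 (SD, n = 2) in wild type and 56.7% ± 1.88 (SD, n = 2) in MZdicer, a difference of -14.5 percentage points, or -22.1 points with 1 mismatch allowed and -7.11 points with each distinct sequence counted once. The unlisted family mir-2190/mir-2198 had 206530 and 169394 CPM in MZdicer against 131 and 33.5 in wild type. It is part of the total and so lowers the listed share in MZdicer. The difference without this family was not computed and may be much smaller. Reads of 21 to 23 nt, the size of miRNAs, made up 73.8% and 95.5% in wild type, 73.9% and 72.4% in MZdicer and 94.8% in MZago2. In wild type 1, 22.6% of reads had 30 to 34 nt. Reads of 25 to 29 nt made up 0.582% and 0.742% in wild type, 14.2% and 8.71% in MZdicer and 1.24% in MZago2. Among reads that matched no listed miRNA, they made up 0.411% and 0.466% in wild type and 24.9% and 16.8% in MZdicer. How many of these came from mir-2190/mir-2198 was not counted. The two-sided exact permutation p was 0.33 for the listed miRNAs and for 25 to 29 nt, the smallest value that 2 against 2 libraries allow, and 0.67 for 21 to 23 nt.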

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

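The items of this part were found by a rule of size, and the tests of explanations in it were chosen after the results had been seen. Reads of precursors that no listed miRNA belongs to were searched for families with 100 CPM or more in every library of a mutant and 10 times the highest wild type library. In MZdicer, 3 families met this. Reads of mir-2190/mir-2198 had 206530 and 169394 CPM in MZdicer against 131 and 33.5 CPM in wild type and 36.7 CPM in MZago2, a difference of 11.44 ± 1.07 (limma, adjusted p = 0.0438). mir-738 had 4664 and 4009 CPM against 25.4 and 18.8, and 1.48 in MZago2 (7.56 ± 0.86, adjusted p = 0.0503). mir-735 had 28526 and 5666 CPM against 545 and 7.06, and 4.28 in MZago2 (7.58 ± 2.35, adjusted p = 0.478). Of alignments to mir-2190 in MZdicer, 31.6% shared the most used 5′ end, and of those to mir-738 38.0%, compared with 99.0% for mir-451.

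The larger share of miR-451 in MZdicer was set against these families, because levels are shares of a fixed total. If a smaller pool of Dicer-made miRNAs were the cause, other precursors that do not need Dicer would gain as much. Of the other families 2, mir-2190/mir-2198 and mir-738, gained at least as much as mir-451 within both adapters. They were found by their gain, their 5′ ends were scattered, and whether they need Dicer was not tested. Their gain therefore does not decide the question. From shares alone, with no amount per embryo known, a larger amount of miR-451 per embryo and a smaller pool of other miRNAs cannot be told apart. The share of miR-451 reads of 24 nt or more was higher in MZdicer by 52.2 percentage points or more within both adapters, and by 38.5 points or more with 3′ ends left free. A biological cause of the longer ends in embryos without Dicer was not tested.

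The near absence of miR-451 in MZago2 could come from less of a transcript shared with mir-144, or from fewer blood cells. Reads of the mir-144 hairpin had a log2 ratio of -1.41 between MZago2 and wild type 2, against -11.53 for miR-451, which argues against either as the whole cause. Depth is argued against too, since 3 reads of MZago2 are worth 0.247 CPM and wild type had 243 CPM or more. A requirement for Ago2 in making or keeping miR-451 remains as a hypothesis, from 1 library of 1 allele.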

How the results depend on the processing

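Alternatives with the adapter term, with precursor families and with both were chosen after seeing the data; the others were planned, and count models, planned for files that hold counts, were not run on these alignments; the planned signatures of long reads and their alternatives were not run. The fit with a replicate block called 47 miRNAs between MZdicer and wild type (15 higher, 32 lower), and the adapter term also called 47, beside 0 without either; 2 pairs of libraries cannot show that the numbers pair the samples by design. The adapter term called 2 between MZago2 and wild type and 37 between the mutants, where the fit without it called 0 and 1. Counting reads per precursor family as aligned called 1 in MZdicer (mir-2190/mir-2198) and 3 between the mutants (these, mir-738 and mir-451), and 41 and 4 with the adapter term too. Between MZago2 and wild type, miR-451 alone passed with reads outside the listed miRNAs as library size and without the MZdicer libraries (1 each). Leaving out single libraries called 0 to 1 between MZdicer and wild type (miR-146a without MZdicer replicate 1), 0 to 1 between MZago2 and wild type and 1 each time between the mutants; lone libraries are then assumed to vary like the other groups. The cause of these changes was not tested, except that block and adapter terms remove the difference between adapters.

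The mean within-adapter difference of miR-451, 5.81, was 5.16 to 6.13 with other denominators or a 16 nt match. Allowing any 3′ end put 22.3% of miR-451 reads at 24 nt or more in wild type 1, 60.8% in MZdicer 1 and 73.9% in MZdicer 2. With 1000 reads per hairpin, 1 arm share lay outside, since the other hairpins listed did not reach this minimum in wild type. Without listed miRNAs the difference at 21 to 23 nt was -27.1 points, and at 25 to 29 nt 20.4 points, or 6.70 points by alignment lines. camera with a preset correlation called 1 list in each contrast of MZago2.

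Of the values of 21 named miRNAs in MZdicer under other settings, 266 kept direction and side of the threshold, 25 passed it and 23 changed sign, each from a difference that had not passed. Starts at the annotated 5′ end gave 0.27 for miR-144-3p and 0.0089 for miR-10b/miR-10d, which had 0.084 with trimmed-mean and 0.10 with median-of-ratios scaling; miR-10a had -0.25 with reads outside the listed miRNAs as library size. Without single libraries the ranges were -3.30 to 1.65 for miR-144-3p, -0.83 to 2.71 for miR-21, -3.23 to 0.26 for miR-20a, -2.21 to 1.0 for miR-1, -2.07 to 0.43 for miR-181a, -0.19 to 0.17 for miR-10b/miR-10d, -0.50 to 1.29 for miR-10a, -1.29 to 0.064 for miR-10c, -1.41 to 8.27 for miR-146a, -0.76 to 5.89 for miR-101a and -0.60 to 4.88 for miR-124.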

Other observations

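Residual miRNA reads in MZdicer differed from wild type at their 3′ ends, depending on the arm they came from; this pattern was noticed in the data, and all tests of it were chosen afterwards. Among miRNAs with 30 reads or more in both libraries, untemplated T at the 3′ end (U in the RNA) was more frequent in MZdicer for 32 of 37 miRNAs of the 3p arm with the first adapter and for 27 of 30 with the second. The median share went from 1.42% to 9.94% and from 1.04% to 8.51%. For miRNAs of the 5p arm the medians were 0.625% and 0.787% with the first adapter and 0.221% and 1.44% with the second, and untemplated T was more frequent in MZdicer for 15 of 41 and for 25 of 33, so with the second adapter most 5p miRNAs gained it too, by less. miR-25 had untemplated T on 2.79% and 1.23% of its reads in wild type and on 42.6% and 29.7% in MZdicer, and miR-199-3p on 1.82% and 1.40% against 44.0% and 24.5%. miR-9-3p had 0.527% and 1.07% against 24.6% and 13.4%, while miR-9-5p of the same hairpin had 4.26% and 1.30% against 2.92% and 3.19%. The miR-9-3p shares cover only exact matches to the hand-written sequence, a minority of its reads in wild type 2 and MZdicer 2. The abundant miR-206, also a 3p miRNA, had 0.847% and 0.369% against 10.7% and 4.68%. These miRNAs were named after their values were seen.

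The 5p arm differed in another way. Reads that ran on into the loop without mismatch, to 25 to 30 nt, made up a larger share in MZdicer for 39 of 40 miRNAs of the 5p arm with the first adapter and 25 of 33 with the second, and a smaller share for 0. Of 3p miRNAs, 3 of 36 and 3 of 26 had a larger share, and 2 and 1 a smaller one.

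Whether adapter remnants or read errors account for the T ends was not settled. With the first adapter, which starts with C, the median gain of 3p miRNAs lay 6.83 percentage points above that of 5p miRNAs. With the second it lay 6.10 points above. These values were part of the pattern as noticed, so they cannot also test it and are given without a p-value. That remnants or errors would reach both arms alike was not tested, and with the second adapter untemplated C also gained more in 3p miRNAs. The smaller gain of 5p miRNAs with the second adapter, which starts with T, was not tested against remnants. That residual reads are pieces of precursors that Dicer had not cut, whose 3p ends were tailed and whose 5p ends run on into the loop, stays open, since it was drawn from these values and no further test of it was made. The same gain was not found for untemplated A (3p minus 5p 0.0602 and -0.146 points), while for C it was 0.0998 and 1.40 points.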
